A study of Homo sapiens with 9 samples.

How the data were processed

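RNA of cell cultures in exponential growth was labelled and hybridised in pairs to 4x44K oligonucleotide arrays, with the derived line in Cy3 and the reference in Cy5 on all 9 arrays and no dye swap. The analysis took 3 arrays of MCF-7:5C, 3 of MCF-7:2A, 1 of MCF-7:WS8 and 1 of MCF-7:PF against MCF-7, and 1 of MCF-7:PF against MCF-7:5C. Per the labels, slide 2 took 2475 ng of Cy3-labelled RNA where the other slides took 1650 ng, and its MCF-7 reference had another labelling yield (19.41 against 15.16 pmol of dye per µg). The replicates of MCF-7:5C came from passages 218 to 220 and those of MCF-7:2A from passages 590 to 592.

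The spot intensities and local backgrounds of both channels were extracted from the scans by the authors with Agilent Feature Extraction 10.5.1.1, per the file headers. The same files hold a log10 ratio of Cy5 over Cy3 per spot, normalised for dye by that software per the file headers. The deposited table gives log2 ratios of Cy3 over Cy5, which the authors derived from the log10 column. On each array between 98.8% and 99.995% of its values lay within 0.01 of that column after the change of base and sign. Between 10.87% and 23.72% of the deposited log2 values were exactly 0. Other deposited columns, such as the flags for spots well above background and for outlying spots, were set by the same software per the file headers. The files name the genome build hg18, and no coordinates are given here.

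Ratios were computed again from the median intensities with R 4.3.3 and limma 3.58.1, with data.table (1.17.8) and jsonlite 2.0.0 for reading and writing. Background was corrected by normexp with an offset of 50. Loess within each array had a span of 0.3, with control and outlying spots at weight 0. Spots of a probe were averaged. Values are log2 of line over reference. Each array held 43376 spots of 41000 probes, controls left out. Probes were named through the RefSeq gene table of assembly GRCh38.p14, used for names and gene order alone. By accession 23434 probes matched, 2392 carried a current symbol and 1030 an older symbol, and 14144 had no symbol and kept their file name. Of the 30973 resulting features, 7520 had more than 1 probe and took the probe with the highest mean intensity over the 9 arrays. A gene was tested where it was well above background in at least 1 channel on at least 3 of the 6 MCF-7:5C and MCF-7:2A arrays, and measured on at least 2 arrays per group.

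The 6 arrays were fitted together with limma (lmFit and eBayes, no trend, not robust), with 4 residual degrees of freedom. Each line's mean log2 ratio was tested against 0, which leaves out the spread of MCF-7 itself, and the difference of the lines' means was tested for MCF-7:5C over MCF-7:2A. All tests were two-sided. A gene was called where its Benjamini-Hochberg adjusted p was below 0.05 and its log2 ratio at least 1 in size. Where a side was well above background on none of its arrays, the fold is given as a lower bound, with the dim side raised, per array and channel, to the lowest signal of any probe well above background. Where that floor did not bring the fold below the fitted one, as for genes at background in MCF-7, the fitted ratio is given and is no bound. Where it was so on 1 or 2 of 3 arrays, the fitted ratio is given, which background may draw toward 0. This holds for FGFR2, CAV1, CYP26A1, FBLN1, LYN and ERBB4 in MCF-7:5C, for FBLN1, IFIT2 and LTB in MCF-7:2A, for TNF in MCF-7:2A in the comparison of the lines, for CD19 and VWF on the lower side of their comparisons, and for PSAT1 in MCF-7 beside MCF-7:2A, while in MCF-7:5C PSAT1 was above background on no array. The 23 gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, over 20001 genes measured on all 6 arrays, adjusted over 69 tests together. For single arrays, genes at 2-fold were counted without a test. The list median was placed among 10000 random lists of equal size and intensity, which describes it and is no p. The MCF-7:PF over MCF-7:5C ratio was counted where the direct and the indirect ratio were both past 2-fold the same way. The overlap of the lines was set beside independent lists, beside 100 simulated pairs of unchanged lines with a shared reference, and beside lines taken from different slides.

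The genes named were those of a rule. For each tested comparison it took the 10 highest and 10 lowest called genes with a symbol that changed the same way on every array and lay well above background, the 3 highest and 3 lowest bounds, up to 4 called members per list, and 11 fixed genes. For single arrays it took the 8 highest and 8 lowest genes, up to 3 members per list and the same 11. Of these the text prints a part. The 23 lists cover estrogen-induced genes, estrogen-repressed genes, the estrogen receptor with partner factors and coregulators, Src family kinases and focal adhesion, growth factor receptors and ligands, interferon-stimulated genes, antigen presentation, and the unfolded protein and integrated stress response. They also cover the BCL2 family and death receptors, cell cycle and DNA replication, luminal epithelial markers, basal and mesenchymal markers, cholesterol and fatty acid synthesis, MAP kinase and AP-1 response, hypoxia and glycolysis, aryl hydrocarbon and retinoid response, p53 targets, and NF-kappa-B and cytokines. The last are the Wnt and Notch pathway, steroid and estrogen metabolism, and markers of fibroblasts, leukocytes and endothelium. Groups, tests, lists and the naming rule were chosen before the data were examined. The minimum of 2 measured arrays per group was chosen after.

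The replicate numbers pair the samples through the slides: replicate 1 of each line was on slide 1 and replicates 2 and 3 on slide 2. The deviations of same-numbered replicates from their group means had correlations across genes of 0.279, 0.267 and 0.201. MCF-7:5C replicate 3 matched MCF-7:2A replicate 2 (0.216) as closely as its own number, so the pairing marks the slide and not the single number. The replicate block called 1667 genes between the lines where the fit without it called 1632.

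The test was tried on simulated data with 200 changed genes among 20001, in 10 simulations with independent genes. At a true log2 ratio of 1.5, 79.8% of changed genes were called for MCF-7:5C over MCF-7, 82.6% for MCF-7:2A over MCF-7 and 61.2% for MCF-7:5C over MCF-7:2A. At 3 the shares were 97.1%, 96.8% and 92.9%. The mean number of false calls was 3.5, 3.1 and 5.9. The simulated arrays were independent of each other, with no shared slide, reference labelling or dye bias, so the number on the real arrays may be higher. Alternatives covered background correction, the ratios of the software and of the deposited table, scaling between arrays, filters and limits, every probe, slide and replicate blocks, each slide alone, each replicate left out, and a dye coefficient over 9 arrays. With no dye swap, the dye coefficient came only from the loop of the MCF-7:5C arrays, the MCF-7:PF array and their joint array. It can thus hold differences between arrays or replicates of MCF-7:5C as well as dye bias. The GC content of probes was not examined because the files hold no probe sequences.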

Results

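Gene expression was measured in 4 cell lines derived from MCF-7, an estrogen receptor positive human breast cancer line whose growth depends on estrogen. MCF-7:5C and MCF-7:2A grow without estrogen and were kept in phenol-red-free medium with charcoal-stripped serum, which is low in estrogens. MCF-7:WS8 depends on estrogen for growth and was kept, like MCF-7 itself, in medium with whole serum. MCF-7:PF, which the labels also list as dependent on estrogen, was kept in the estrogen-poor medium with added estradiol and PP2, an inhibitor of the kinase c-Src. Each of 9 two-colour oligonucleotide arrays carried Cy3-labelled RNA of a derived line beside a Cy5-labelled reference. The reference was RNA of untreated MCF-7 on 8 arrays and RNA of MCF-7:5C on 1 array of MCF-7:PF. MCF-7:5C and MCF-7:2A had 3 replicates each, from different passages, and MCF-7:WS8 and MCF-7:PF had 1 array per comparison. Between 59.58% and 79.6% of probes per array lay well above background in Cy3, and between 56.02% and 71.85% in Cy5. No spot was saturated. The number of arrays limits the precision. Replicate 1 of MCF-7:5C and of MCF-7:2A shared a slide with both MCF-7:PF arrays (slide 1), replicates 2 and 3 of both lines shared another (slide 2), and MCF-7:WS8 was on another slide. The slide 2 replicates resembled each other more than replicate 1. The standard deviation of the log2 difference between a pair of replicates was 0.242 in MCF-7:5C and 0.176 in MCF-7:2A within slide 2. Between slides it was 0.568 to 0.591 in MCF-7:5C and 0.72 to 0.725 in MCF-7:2A.

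The comparison of MCF-7:5C with MCF-7 asked how a line that grows without estrogen differs from its parent, each in its own medium. MCF-7 was kept with whole serum and MCF-7:5C in estrogen-poor medium, so line and medium cannot be told apart. Estrogen-induced genes were lower in MCF-7:5C, and interferon-stimulated and antigen presentation genes were higher. These list shifts were called at a preset correlation of the genes and not at an estimated one. Of 39 estrogen-induced genes tested, 22 fell and 0 rose, with a median log2 ratio of -1.42. Of 42 interferon-stimulated genes, 30 rose and 2 fell, with a median log2 ratio of 1.43. Among called genes with a symbol that were well above background in both channels, the osteoprotegerin gene TNFRSF11B was highest, with a log2 ratio of 5.04 ± 0.26 (SE, n = 3, adjusted p = 3.16e-05). The ephrin receptor gene EPHA4 was near the lowest at -6.10 ± 0.217 (adjusted p = 1.13e-05), below which stood only the long noncoding RNA gene LINC00052 at -6.38.

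The estrogen-induced genes that fell in MCF-7:5C included CCN5 (log2 ratio -5.07), CALCR, the calcitonin receptor (-4.70), FHL2 (-3.90) and AREG, an EGFR ligand (-3.70). GREB1, an estrogen receptor cofactor, fell to -2.58 and CXCL12, a chemokine, to -3.37. PGR, the progesterone receptor, was not well above background in MCF-7:5C and was at least 3.7-fold lower. TFF1, a secreted trefoil protein, had a log2 ratio of -0.92, under the fold limit. It was called with the slide as a block (-1.04, adjusted p = 0.00499) and without MCF-7:5C replicate 2 (-1.30, adjusted p = 0.00838). The list shift was called with camera at its preset correlation (adjusted p = 9.71e-12), and not otherwise (adjusted p = 0.3 with an estimated correlation). Its median was -1.56 on slide 1 and -1.38 on slide 2. ESR1, the estrogen receptor itself, rose by 1.02 ± 0.165. The ESR1 value was 0.88 without replicate 1 and 0.98 without replicate 3 of MCF-7:5C, and 0.98 and 0.94 with the ratios of the scanner software and of the deposited table, all under the fold limit. Among 23 genes of the estrogen receptor, its partner transcription factors and coregulators, 1 rose and 3 fell, among them the corepressors NRIP1 (-2.38) and NCOR2 (-1.19). Of 14 estrogen-repressed genes 3 rose and 3 fell, for example TXNIP (2.14) and the caveolin gene CAV1 (-1.92). Their median was 1.08 on slide 1 and -0.48 on slide 2, and TXNIP stood at 1.23 without MCF-7:5C replicate 1.

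The interferon-stimulated genes that rose in MCF-7:5C included XAF1 (4.30), IFI44L (3.58), OAS2 (3.22) and IFI44 (2.63), all induced in the antiviral response. IFITM1 rose by 1.35 ± 0.325, and by 0.79, under the fold limit, without MCF-7:5C replicate 1. Of 17 antigen presentation genes 7 rose and 0 fell, including the HLA class I genes HLA-B (2.02), HLA-F (1.96) and HLA-C (1.78) and the peptide transporter gene TAP1 (1.77). Both lists shifted upward with camera (adjusted p = 2.23e-10 and 5.94e-05), but not with the other form of the test (adjusted p = 0.489 and 0.339 with an estimated correlation). The interferon median was 1.75 on slide 1 and 1.34 on slide 2, and the antigen presentation median 1.08 and 0.82. The aryl hydrocarbon and retinoid response list shifted downward, with 5 of 17 genes lower, 0 higher and a median of -0.47 (adjusted p = 0.0158 with the preset and 0.526 with an estimated correlation). It held the ligand-activated receptor gene AHR (-2.84), the estrogen-hydroxylating enzyme gene CYP1B1 (-2.73) and the retinoic acid hydroxylase gene CYP26A1 (-1.27).

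The other lists did not shift as a whole in MCF-7:5C, although single members changed. Of 26 growth factor receptors and ligands 4 rose and 6 fell, with FGFR4 at 2.51, FGFR2 at -3.31 and IGF1R at -2.64. ERBB2, the HER2 receptor, rose by 1.08 ± 0.289, and by 0.59, under the fold limit, without MCF-7:5C replicate 1. EGFR was at background in MCF-7 and on 2 of 3 arrays in MCF-7:5C, so no ratio is given. Of 24 Src family kinase and focal adhesion genes 3 fell and 0 rose, including the kinase gene LYN (-1.64) and the integrin gene ITGB4 (-1.32), and SRC itself stood at -0.57. By the ratios of the deposited table SRC passed (-1.025, adjusted p = 0.0214). Of 27 luminal epithelial markers 7 rose, such as MUC1 (2.05), and 5 fell. Among those that fell were AGR2 (-3.36) and TFF3 (-2.28, or -0.81 in the fit with a dye coefficient). The luminal list had a median of 0.10 and a mean of -0.12, with the test pointing down. Of 24 basal and mesenchymal markers 2 rose, among them TWIST1 (3.38), and 5 fell, among them TGFBI (-3.97), with a median of 0.02 against a mean of -0.11. TGFBI stood at -2.07 in the fit with a dye coefficient. Among 34 BCL2 family and death receptor genes 2 rose and 2 fell. BCL2, which blocks apoptosis, fell by 2.06 on the probe tested, while its 1 other probe had the opposite sign. Of 25 MAP kinase and AP-1 response genes 2 rose and 4 fell, including JUN (-2.42), and MYC stood at 0.38. In the unfolded protein and integrated stress response 4 of 31 rose and 1 fell, with HERPUD1 at 2.45. In steroid and estrogen metabolism 2 of 18 rose, among them the catechol estrogen methyltransferase gene COMT (2.32), and 2 fell.

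For the remaining lists in MCF-7:5C, 3 of 25 p53 targets rose and 2 fell, and 3 of 23 hypoxia and glycolysis genes rose with 0 lower, such as BNIP3L (1.93). Of 23 Wnt and Notch pathway genes 3 rose and 2 fell, with a median of -0.16 and a mean of 0.09. Of 15 NF-kappa-B and cytokine genes only TNFAIP2 fell (-2.97) and 0 rose. Of 32 cholesterol and fatty acid synthesis genes 0 rose and 2 fell. The marker lists of other cell types showed 1 lower of 6 fibroblast genes (FBLN1, -3.48), 1 higher of 6 leukocyte genes (CD19, 2.43) and 1 higher of 6 endothelial genes (VWF, 1.09). The leukocyte list had a median of -0.10 and a mean of 0.30. Of 40 cell cycle and DNA replication genes 0 rose and only the proliferation marker MKI67 fell (-1.01), and 0 fell when adjusted over the list alone. Without MCF-7:5C replicate 1, MKI67 stood at -0.59, and without background subtraction at -0.975, both under the fold limit. The cell cycle median of 0.03 hid a difference between slides, -0.67 on slide 1 and 0.41 on slide 2, and was -0.78 in the fit with a dye coefficient. Without replicate 1 the list shifted upward at the preset correlation (median 0.41, adjusted p = 0.00928). On all arrays it was not called (adjusted p = 0.807, or 0.95 with the estimated correlation of 0.683). Adjusted over the list alone, the counts of the other 22 lists were the same in MCF-7:5C. Median and mean also differed in sign for the BCL2 family (0.12 and -0.05) and steroid metabolism (-0.07 and 0.00).

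Over all genes, 2754 of 20227 tested differed between MCF-7:5C and MCF-7, 1470 higher and 1284 lower, by limma with a minimum of 2-fold. Of these, 2703 changed the same way on every array. Outside the lists, the iron carrier gene TF, which encodes transferrin (4.62), the transmembrane gene TM4SF1 (4.56), the calcium-binding gene S100A8 (3.95) and the cancer-testis gene GAGE12F (3.86) were among the highest. The protease gene PRSS23 (-5.77), the galectin gene LGALS1 (-5.22), the lipid phosphatase gene INPP4B (-5.18) and the coagulation inhibitor gene TFPI (-4.74) were among the lowest. NPY1R, a neuropeptide Y receptor, was at least 29.6-fold lower, at background in MCF-7:5C. With the slide as a block 2846 genes were called, 2609 of them shared with the fit without it. Slide 2 alone gave 2875 called genes, and slide 1 gave 4059 at 2-fold from its 1 array with no test. Because the line was in Cy3 on every MCF-7 array, gene-specific dye bias did not cancel. A fit of all 9 arrays with a dye coefficient called 499 genes, at a median standard error of 0.381 in place of 0.156. In it 2727 of the 2754 genes kept their sign, 1960 of them at 2-fold or more. The dye coefficient itself was called for 0 genes. As it also holds differences between arrays, values from this fit cannot be read as corrected for dye alone.

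MCF-7:2A was compared with MCF-7 for the same purpose, and line and medium again changed together. Interferon-stimulated genes, which were higher in MCF-7:5C, were lower in MCF-7:2A: 35 of 42 fell and 0 rose, with a median log2 ratio of -2.24. Estrogen-induced genes were again lower, with 15 of 39 down, 1 up and a median of -0.71 across the list. Targets of p53 were higher, with 9 of 25 called up, 0 down, 16 not called and a median of 0.69. With an estimated correlation none of these 3 list shifts was called (adjusted p = 0.302, 0.339 and 0.526). The nuclear envelope gene SYNE1 was highest at 6.09 ± 0.16 (SE, n = 3, adjusted p = 5.17e-06), and the glutathione transferase gene GSTM3 lowest at -6.73 ± 0.269 (adjusted p = 1.59e-05).

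The interferon-stimulated genes that fell furthest in MCF-7:2A were IFIT1 (-5.95 ± 0.145, adjusted p = 5.17e-06), IFI44 (-5.76), IFIT2 (-5.59) and IFI6 (-5.38). IFI44L was at background and at least 15.6-fold lower. IFITM1 fell to -3.56. The list shifted with camera (adjusted p = 1.76e-21 with the preset and 0.302 with an estimated correlation), and its median was -1.84 on slide 1 and -2.43 on slide 2. Antigen presentation genes shifted the same way with 2 of 17 lower, HLA-A (-1.66) and HLA-F (-1.60), and 0 higher (median -0.34, adjusted p = 0.00465, or 0.514 with an estimated correlation). Their median was -0.24 on slide 1 and -0.54 on slide 2. Of 15 NF-kappa-B and cytokine genes 5 fell and 0 rose (median -0.32, adjusted p = 0.0106, or 0.36 with an estimated correlation). The median was -0.30 on slide 1 and -0.53 on slide 2. The genes that fell included the lymphotoxin gene LTB (-1.80), the NF-kappa-B subunit gene RELB (-1.41) and the chemokine gene CCL5, which was at least 6.1-fold lower. None of 6 leukocyte genes was called, and of 6 fibroblast genes only FBLN1 fell (-3.23), while of 6 endothelial genes only VWF rose (1.11).

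Among estrogen-induced genes, CCN5 (-5.94), CXCL12 (-4.10), PDZK1 (-4.08), FHL2 (-3.95) and GREB1 (-2.16) fell in MCF-7:2A, while PGR had a log2 ratio of 0.15 and TFF1 of 0.00. The list shift was called at the preset correlation (adjusted p = 5.88e-06) and not otherwise (adjusted p = 0.339 with an estimated correlation), and its median was -0.85 on slide 1 and -0.93 on slide 2. ESR1 rose by 1.62 ± 0.165. The p53 targets that rose included the desmosomal gene PERP (2.29), the ribonucleotide reductase subunit gene RRM2B (1.88) and ZMAT3 (2.18, from background in MCF-7). That list passed at the preset correlation (adjusted p = 0.00157, or 0.526 with an estimated correlation), with a median of 0.38 on slide 1 and 1.05 on slide 2. Of 18 steroid and estrogen metabolism genes 6 rose and 1 fell (median 0.54), among them the aldo-keto reductase genes AKR1C3 (2.91) and AKR1C1 (2.62), the drug efflux gene ABCG2 (2.30) and COMT (2.18). The steroid list passed narrowly (adjusted p = 0.0335, or 0.489 with an estimated correlation). It no longer passed without MCF-7:5C replicate 1 (adjusted p = 0.0685), without MCF-7:2A replicate 1 (0.158), within slide 2 (0.212), or with the ratios of the scanner software (0.0599) or of the deposited table (0.0851).

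Members of lists that did not shift as a whole also changed in MCF-7:2A. Of 26 growth factor receptors and ligands 6 rose and 4 fell. FGFR3, a fibroblast growth factor receptor, rose by 2.65 and AREG fell to -2.50. ERBB2 had a log2 ratio of 0.47. EGFR, at background in MCF-7, had a fitted ratio of 0.57 and was not called. It was called at 2.00 with the ratios of the software (adjusted p = 0.00241) and of the deposited table (adjusted p = 0.00229). Basal and mesenchymal markers went up in 5 and down in 2 of 24, with the intermediate filament gene VIM at 3.02 and the integrin gene ITGA6 at 2.25, a median of -0.04 and a mean of 0.18. Luminal markers went up in 7 and down in 4 of 27, with TFF3 at 2.06, or 1.32 without MCF-7:2A replicate 1. Of 25 MAP kinase and AP-1 response genes 1 rose and 7 fell, including the phosphatase gene DUSP5 (-2.28) and JUN (-1.55), and MYC, a proliferation-driving transcription factor, fell by 1.34. This list was not called (median -0.22, adjusted p = 0.0595). It passed without MCF-7:5C replicate 1 (0.0448), without MCF-7:2A replicate 1 (0.0198) or replicate 2 (0.0454), and within slide 2 (0.0224), at the preset correlation. With an estimated correlation its adjusted p on all arrays was 0.594. BCL2 fell by 1.44, and stood at -0.91, under the fold limit, without MCF-7:2A replicate 1. Of 17 aryl hydrocarbon and retinoid response genes 2 rose, among them AHR (1.46), and 4 fell, among them CYP26A1 (-1.08, and -0.91 without background subtraction), with a median of 0.14 and a mean of -0.13. The serine synthesis gene PSAT1 rose by 3.94, the Wnt effector gene LEF1 rose by 3.64 from background in MCF-7, and SRC stood at 0.03. Higher and lower genes numbered 2 and 0 of 24 in the Src list, 3 and 1 of 23 in the estrogen receptor and coregulator list, and 2 and 1 of 14 among estrogen-repressed genes. They numbered 3 and 4 of 34 in the BCL2 family, 4 and 2 of 31 in the stress response, 2 and 2 of 23 in the Wnt and Notch pathway, and 1 and 1 of 23 in hypoxia and glycolysis. The estrogen receptor and estrogen-repressed lists had medians of 0.01 and 0.02, with the test pointing down. The estrogen-repressed median was -0.06 on slide 2 and 0.82 in the fit with a dye coefficient. Of 32 cholesterol and fatty acid synthesis genes 2 rose and 1 fell, and that list passed only without MCF-7:2A replicate 3 (adjusted p = 0.0328 at the preset correlation, against 0.0935 on all arrays and 0.718 there with an estimated one). Cell cycle genes included 2 higher of 40, and 1 adjusted over the list alone. Their median was 0.25, and -0.56 in the fit with a dye coefficient. The counts of the other 22 lists were the same in MCF-7:2A when adjusted over the list alone.

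Over all genes, 2391 of 20227 differed between MCF-7:2A and MCF-7, 1246 higher and 1145 lower, and 2361 changed the same way on every array. The protocadherin gene PCDH9 (5.42), the annexin gene ANXA1 (3.98), the pluripotency factor gene SOX2 (3.67) and the nuclear receptor gene NR2F1 (3.61) were among the highest. The calcium-binding gene S100A6 (-5.26) and the metalloproteinase inhibitor gene TIMP1 (-4.71) were among the lowest. TCEAL8 and PCDH19, both at background in MCF-7, had fitted ratios of 5.53 and 5.34. With the slide as a block 2589 genes were called, 2257 of them shared. Slide 2 alone gave 2755 and slide 1 gave 3754 at 2-fold with no test. The 9-array fit with a dye coefficient called 100 genes, at a median standard error of 0.44, and 2361 of the 2391 genes kept their sign, 1681 of them at 2-fold or more.

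MCF-7:5C and MCF-7:2A were then compared with each other, where the dye and the reference are the same on both sides. Their largest difference among the lists was in interferon-stimulated genes: 37 of 42 were higher in MCF-7:5C, 38 when adjusted over the list alone, and 0 were lower. The median log2 difference was 3.70. IFIT1 was higher by 8.56 ± 0.205 (SE, n = 3 against 3, adjusted p = 6.21e-06) and IFI44 by 8.38 ± 0.196 (adjusted p = 6.21e-06). IFI44L was at least 177-fold higher and RIGI, a sensor of viral RNA, was higher by 5.52. LGALS1 was lowest at -5.63 ± 0.283 (adjusted p = 9.29e-05), followed by SOX2 at -5.43.

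The interferon difference passed camera with an adjusted p of 4.49e-38 at the preset correlation and did not pass otherwise (adjusted p = 0.3 with an estimated correlation). The interferon median was 3.54 on slide 1 and 3.69 on slide 2. Antigen presentation genes were higher in 9 of 17 and lower in 0 (median 1.13, adjusted p = 2.28e-09, or 0.3 with an estimated correlation), with HLA-F at 3.55, HLA-A at 2.96 and HLA-B at 2.74. Of 15 NF-kappa-B and cytokine genes 6 were higher and 0 lower (median 0.51, adjusted p = 0.000756, or 0.302 with an estimated correlation), with LTB at 2.23, TNF at 1.28 and CCL5 at least 6.05-fold higher. Src family kinase and focal adhesion genes were lower in 4 of 24 and higher in 0 (median -0.36, adjusted p = 0.00384, or 0.302 with an estimated correlation). These 4 were PAG1, a membrane adaptor that holds a Src inhibitor kinase (-2.53), ITGB4 (-1.84), ITGAV (-1.47) and CAV1 (-1.26). CAV1 did not pass without MCF-7:5C replicate 3 (adjusted p = 0.0516), and SRC stood at -0.61 without passing. Of 6 leukocyte genes CD19 was higher (2.40) and none was lower.

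Estrogen-induced genes were lower in MCF-7:5C than in MCF-7:2A in 6 of 39 and higher in 2 (median -0.43, adjusted p = 0.00465, or 0.526 with an estimated correlation). PKIB stood at -3.89 and TPBG at -2.89, PGR was at least 4.12-fold lower, and MYB was higher by 1.34. The differences in ESR1 (-0.60), TFF1 (-0.92), GREB1 (-0.42), CXCL12 (0.74), ERBB2 (0.60), EGFR (-0.63) and BCL2 (-0.62) did not pass with all arrays. Some of them passed otherwise. CXCL12 stood at 1.57 within slide 2 (adjusted p = 3.16e-05) and at 1.28 without MCF-7:2A replicate 1 (0.0335), and BCL2 at -1.125 (0.000643) and -1.15 (0.00877). TFF1 stood at -1.30 without MCF-7:5C replicate 2 (0.0446). EGFR, above background on 1 of 3 MCF-7:5C arrays, stood at -2.09 with the ratios of the software (0.0223) and at -2.06 with those of the deposited table (0.0249). MYC was higher in MCF-7:5C by 1.72 and IFITM1 by 4.91. AHR (-4.30), CYP1B1 (-3.43), the EGFR family receptor gene ERBB4 (-4.42), VIM (-2.62), AGR2 (-3.02) and TFF3 (-4.34) were lower. Without MCF-7:2A replicate 1, TFF3 stood at -3.59 and CYP1B1 at -2.82. Luminal markers included 1 higher and 5 lower of 27, with a median of 0.06 and a mean of -0.38. Among steroid metabolism genes 5 of 18 were lower and 0 higher, including AKR1C1 (-3.36) and AKR1C3 (-3.12), with a median of -0.01 and a mean of -0.68. That list was not called (adjusted p = 0.0935), and passed without MCF-7:2A replicate 2 (0.0409), at the preset correlation, against 0.526 on all arrays with an estimated one. PSAT1, at background in MCF-7:5C, had a fitted difference of -4.02. Of 25 p53 targets 4 were lower and 0 higher (adjusted p = 0.0653, or 0.718 with an estimated correlation). The p53 median was 0.22 on slide 1 and -0.50 on slide 2. At the preset correlation the list passed only where slide 1 arrays were left out, without MCF-7:5C replicate 1 (0.0306), without MCF-7:2A replicate 1 (0.00293) and within slide 2 (0.00101). The estrogen-repressed list, with 2 of 14 lower and 0 higher, also changed sign between slides (0.43 and -0.40). It passed within slide 2 (0.0401) and without MCF-7:5C replicate 1 (0.0297), against 0.318 on all arrays and 0.929 there with an estimated correlation. The cell cycle list, with a median of -1.04 on slide 1 and 0.16 on slide 2, passed without MCF-7:5C replicate 2 (0.0103) or 3 (0.0129), against 0.22 on all arrays and 0.929 there with an estimated correlation.

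Over all genes 1632 of 20227 differed, 820 higher and 812 lower in MCF-7:5C. Leaving out MCF-7:5C replicate 3 gave 1054. With the slide as a block 1873 genes were called, 1630 of them shared. Slide 2 alone gave 1947, and slide 1 gave 4682 at 2-fold with no test. With the replicate number as a block the count was 1667, and IRS2 (log2 difference 1.91) lost its call (adjusted p = 0.0644), as did HES1 (1.43, adjusted p = 0.0722), ABCG2 (-1.65, adjusted p = 0.069) and ANKRD37 (1.06, adjusted p = 0.0564). Without MCF-7:5C replicate 3 their adjusted p values were, in that order, 0.12, 0.0961, 0.146 and 0.149.

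**Figure D1:**
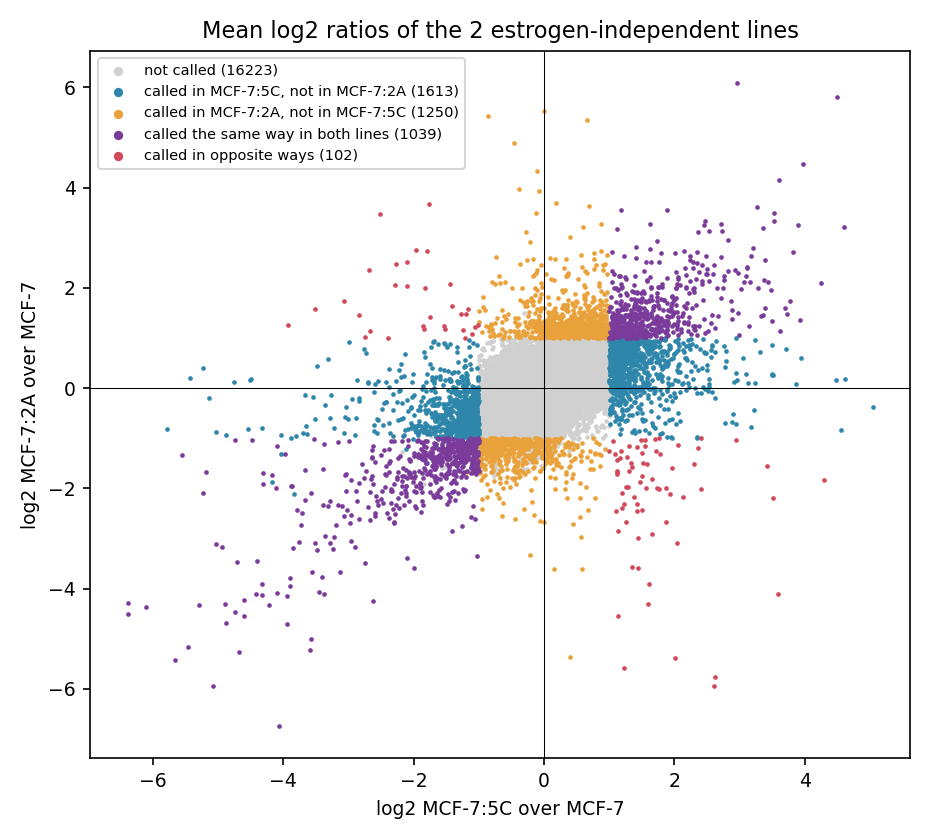
Mean log2 ratio of each tested gene in MCF-7:5C over MCF-7 (x axis) and in MCF-7:2A over MCF-7 (y axis), 3 arrays each, with 1 point per gene coloured by the call in each line. The 1039 genes called the same way lie on the rising diagonal, and the 102 called in opposite ways lie in the other quadrants.

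The genes changed in both lines were counted to see how far the estrogen-independent lines share differences from MCF-7. Of 20227 genes, 510 were higher in both and 529 lower in both, where independent lists of these sizes would share 90.55 and 72.68. Of the 510, 302 were also at least 2-fold higher in MCF-7:WS8 and 329 in MCF-7:PF, on 1 array each. Of the 529, 287 and 319 were at least 2-fold lower there. Many of the shared genes are thus not particular to the lines that grow without estrogen. In opposite directions, 70 were higher in MCF-7:5C and lower in MCF-7:2A and 32 the reverse, against 83.21 and 79.1 for independent lists. Interferon-stimulated genes made up 26 of those higher in MCF-7:5C and lower in MCF-7:2A, and 14 estrogen-induced genes were lower in both. Both comparisons used MCF-7 as reference. Simulated unchanged lines against the shared reference gave on average 0 genes called the same way in both, over 100 simulations. Their mean log2 ratios had a correlation across genes of 0.438 and a covariance of 0.0312, against 0.554 and 0.312 observed, and genes are not independent replicates. The simulation held only labelling error and array error, so 0 calls past 2-fold was to be foreseen. It held no dye bias and no trait of the MCF-7 RNA itself, so it cannot exclude the shared reference as a source of the overlap. Lines were also set against different labellings of MCF-7, still in the same dye, by 2-fold alone. There 1139 genes were shared between MCF-7:5C replicate 1 and MCF-7:2A replicates 2 and 3, and 858 between the reverse choice. The 9-array fit with a dye coefficient left 59 shared genes.

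**Figure D2:**
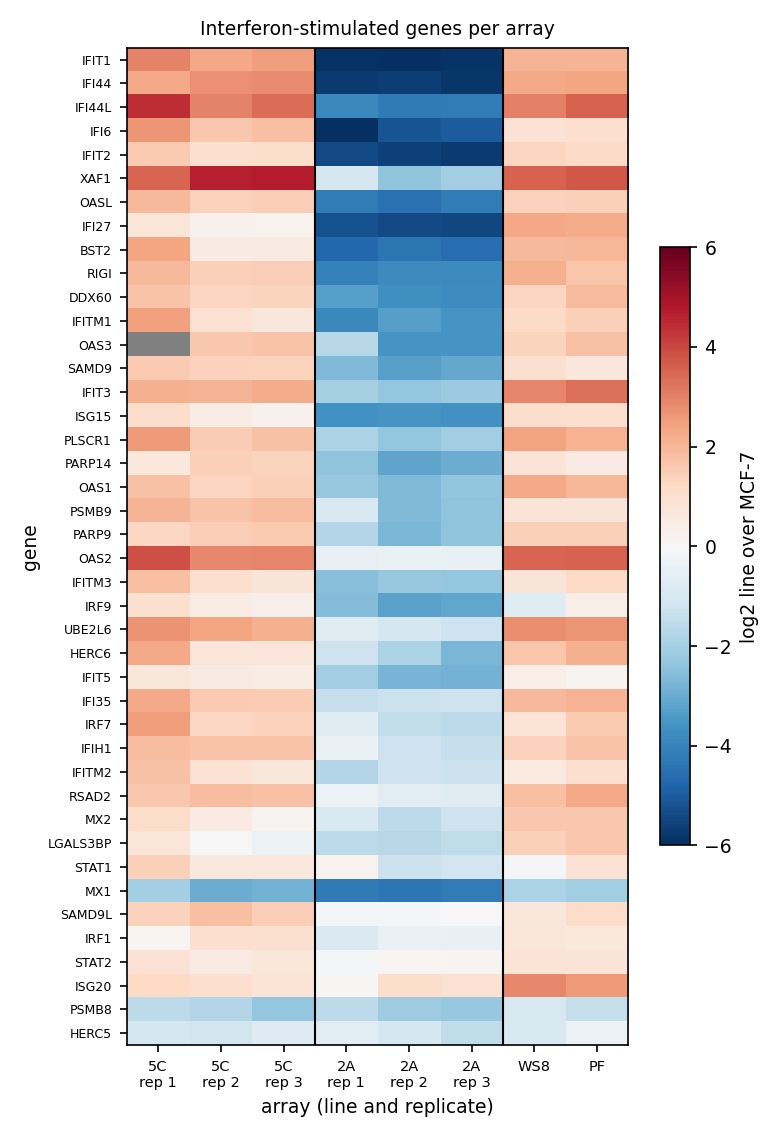
Log2 ratio over MCF-7 (colour scale) of each tested interferon-stimulated gene (rows) on each array (columns), grey where a gene was not measured. Most genes are above 0 on the 3 MCF-7:5C arrays and below 0 on the 3 MCF-7:2A arrays, and the list medians per array run from 1.29 to 1.75 and from -2.52 to -1.84.

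MCF-7:WS8 was compared with MCF-7 as another estrogen-dependent line in the same medium, on 1 array with no replicate and therefore no test. Interferon-stimulated genes and genes of the unfolded protein and integrated stress response lay higher, and cell cycle and estrogen-induced genes lower. The fibrinogen gene FGG had a log2 ratio of 6.77, the adhesion gene CEACAM6 of 6.54 and the urea cycle gene CPS1 of 6.39. At the other end stood the chemokine receptor gene ACKR3 at -8.41 and the matrix gene EFEMP1 at -5.67. At 2-fold, 2131 of 22491 measured genes were higher and 1692 lower. Of 42 interferon-stimulated genes 26 were higher and 1 lower (median 1.35, above all of 10000 random lists matched on intensity), with XAF1 at 3.53 and OAS2 at 3.47. Of 30 stress response genes 16 were higher and 0 lower (median 1.05, percentile 100), with HERPUD1 at 3.35 and the asparagine synthetase gene ASNS at 2.62. The aryl hydrocarbon and retinoid response list had a median of 0.83 (percentile 100), with CYP1B1 at 3.61, and the p53 target GDF15 stood at 4.40. Of 40 cell cycle genes 15 were lower and 0 higher (median -0.86, percentile 0), including NUSAP1 (-1.96) and CENPA (-1.87). Within MCF-7:5C the median of this list went from -0.67 on slide 1 to 0.41 on slide 2. One array thus cannot tell a trait of the line from such a difference between replicates. The random lists also leave out the correlation of these genes, estimated at 0.683. Of 40 estrogen-induced genes 17 were lower and 5 higher (median -0.64, percentile 0), with PDZK1 at -4.82 and TPBG at -4.40, although TFF1 was at 2.60 and GREB1 at 0.16. ESR1 was at -1.13, the membrane estrogen receptor gene GPER1 at -4.17, GATA3, a luminal transcription factor, at -3.46, ERBB2 at 2.46 and BCL2 at -2.53.

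MCF-7:PF over MCF-7, also 1 array, gave a similar profile. CEACAM6 (6.44), FGG (6.22) and the ceruloplasmin gene CP, which encodes a copper-carrying plasma protein (5.95) were highest, and ACKR3 (-8.76), EFEMP1 (-6.44) and the polo-like kinase gene PLK2 (-6.01) lowest. Of 21839 measured genes 2069 were at least 2-fold higher and 1641 lower. Interferon-stimulated genes had a median of 1.59 with 31 of 42 higher and 2 lower, and the stress response list 0.92 with 13 of 30 higher. Cell cycle genes had a median of -0.87 with 15 of 40 lower, including the topoisomerase gene TOP2A (-1.64). The limit given for that list in MCF-7:WS8 holds here too. Estrogen-induced genes had a median of -0.89 with 19 of 39 lower and 6 higher, in medium with added estradiol. TFF1 was at 2.22, GREB1 at 0.59, PGR at 0.84, CXCL12 at -3.63, BCL2 at -3.56 and ERBB2 at 1.91. Steroid metabolism genes had a median of 0.79 with 9 of 21 higher. Across the 21348 genes measured on the MCF-7:WS8 and MCF-7:PF arrays the log2 ratios had a correlation of 0.906. Of these genes 1615 were at least 2-fold higher in both and 1129 lower in both, where independent lists would share 206 and 123.3, 0 were opposite, and 432 differed by 2-fold. The arrays shared the MCF-7 reference, from which part of the excess may come.

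**Figure D3:**
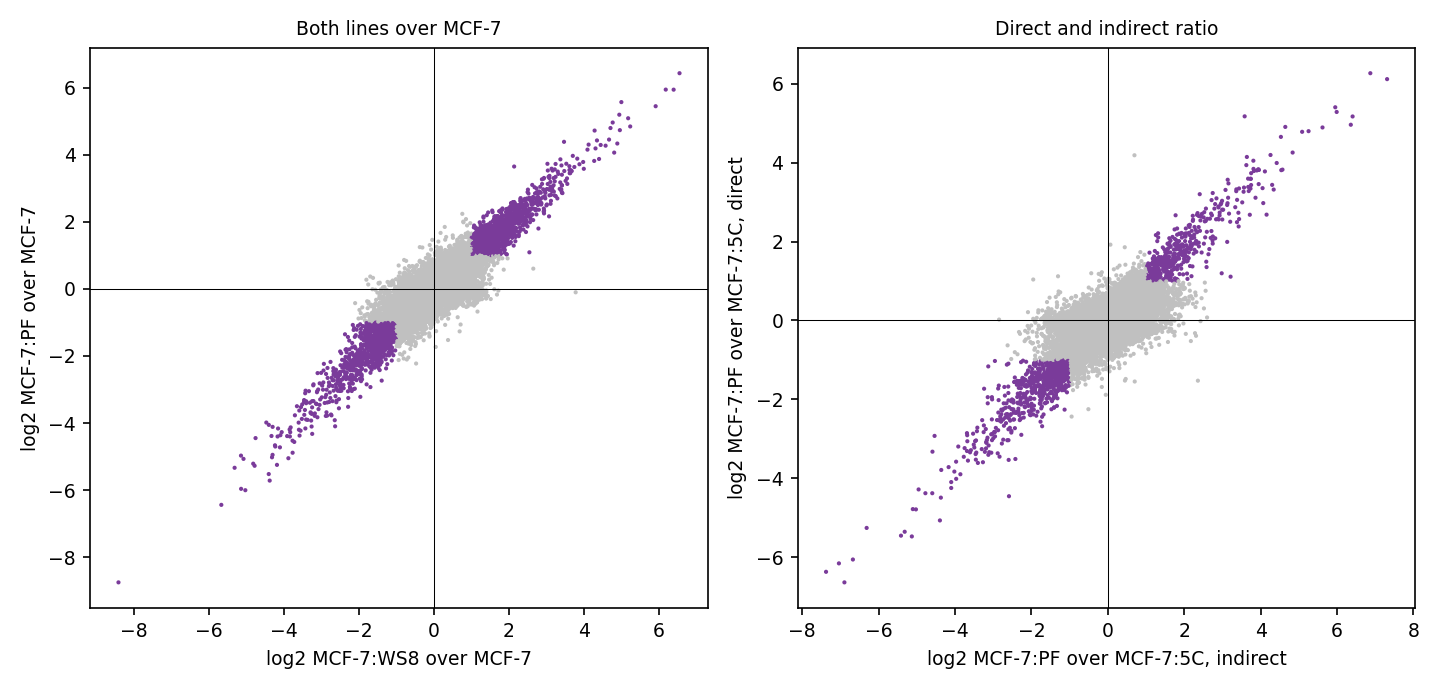
Log2 ratios of single arrays, 1 point per gene. Left, MCF-7:WS8 over MCF-7 (x axis) against MCF-7:PF over MCF-7 (y axis), with the 1615 higher and 1129 lower in both at 2-fold in purple; right, the MCF-7:PF over MCF-7:5C ratio from the arrays against MCF-7 (x axis) and from their joint array (y axis), with the 551 higher and 736 lower at 2-fold in both in purple.

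MCF-7:PF and MCF-7:5C were hybridised together to compare cells kept with estradiol and the c-Src inhibitor with cells kept without either. Genes responding to aryl hydrocarbons and retinoids and a subset of estrogen-induced genes were higher in MCF-7:PF, while 2 of 41 interferon-stimulated genes differed. A gene was counted where the direct ratio and the indirect ratio, from the MCF-7:PF and MCF-7:5C replicate 1 arrays against MCF-7, were both at least 2-fold the same way, which held for 551 higher and 736 lower of 22680 genes. The direct ratio alone gave 1670, the indirect ratio alone 2932, and 4 genes were opposite. The mean of both ratios was 6.72 for MUCL1, 6.57 for CYP1B1, 5.79 for TGFBI and 5.66 for TFF3, and -6.88 for the Wnt inhibitor gene DKK1, -6.77 for TNFRSF11B and -6.60 for PLK2.

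Of 39 estrogen-induced genes 10 were higher and 4 lower in MCF-7:PF than in MCF-7:5C. The list median, taken over each gene's mean of the direct and the indirect ratio, was 0.47, above all random lists. The other list medians of this comparison were taken the same way. PKIB had a direct ratio of 4.05, SLC7A5 of 3.44, GREB1 of 2.87 and TFF1 of 2.68, while CXCL12 stood at 0.01. PGR, at background in MCF-7:5C, had a direct ratio of 2.89. ESR1 had a direct ratio of -2.46, GPER1 of -4.49 and BCL2 of -2.05. Of 17 aryl hydrocarbon and retinoid response genes 9 were higher and 1 lower (median 1.59, percentile 100), with CYP26A1 at 3.74 and AHR at 3.44. Of 30 stress response genes 5 were higher and 0 lower (median 0.53, percentile 100). Of 41 interferon-stimulated genes 2 were higher and 0 lower (median -0.14, percentile 6.8), and of 40 cell cycle genes 0 were higher or lower (median -0.05). The early response genes EGR1 (-3.04) and FOS (-2.83) were lower. SRC (-0.26), ERBB2 (0.02), MYC (0.01) and IFITM1 (-0.40) did not pass 2-fold in both ratios. EGFR was at background in MCF-7:5C, which sets no upper limit to its ratio.

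The return of MCF-7:5C differences in MCF-7:PF was measured on genes chosen on MCF-7:5C replicates 2 and 3, which were on other arrays. Of 1410 genes higher in MCF-7:5C than in MCF-7, 271 (19.2%, Wilson 95% interval 17.2% to 21.4%) were at least 2-fold lower in MCF-7:PF than in MCF-7:5C, 68 were at least 2-fold higher, further from MCF-7, and 769 were still at least 2-fold from MCF-7 in MCF-7:PF. Of 1379 genes lower in MCF-7:5C, 151 (10.9%, interval 9.41% to 12.7%) were at least 2-fold higher in MCF-7:PF, 100 were at least 2-fold lower, further from MCF-7, and 670 were still 2-fold from MCF-7. The median log2 ratio of MCF-7:PF over MCF-7:5C was -0.24 for the higher genes, 63.8% of which moved toward MCF-7, and -0.01 for the lower genes, of which 49.5% did. Together 422 of 2789 (15.1%) went back, beside 997 of 17225 genes not called in MCF-7:5C (5.79%) that differed by 2-fold either way. Going back can include passing MCF-7. In MCF-7:PF, 19 of the higher genes stood at least 2-fold below MCF-7 and 41 of the lower genes at least 2-fold above it. By list, 5 of 6 aryl hydrocarbon and retinoid response genes that were lower went back, as did 4 of 4 in steroid metabolism and 6 of 21 estrogen-induced genes, but 0 of 24 interferon-stimulated and 0 of 8 antigen presentation genes that were higher. Over MCF-7, the whole aryl hydrocarbon and retinoid list had a median of 0.82 in MCF-7:PF and the steroid list 0.79 (percentile 100 each). Such genes may thus have risen past MCF-7 and not returned to its level. The intervals cover counting of genes only, and genes are not independent. MCF-7:5C was in Cy3 on the arrays that chose the genes, and MCF-7:PF was in Cy3 on both of its arrays. A gene-specific dye bias would thus give the direct ratio the sign of the MCF-7:5C ratio. It could lower the shares that went back and raise the counts still 2-fold from MCF-7.

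**Figure D4:**
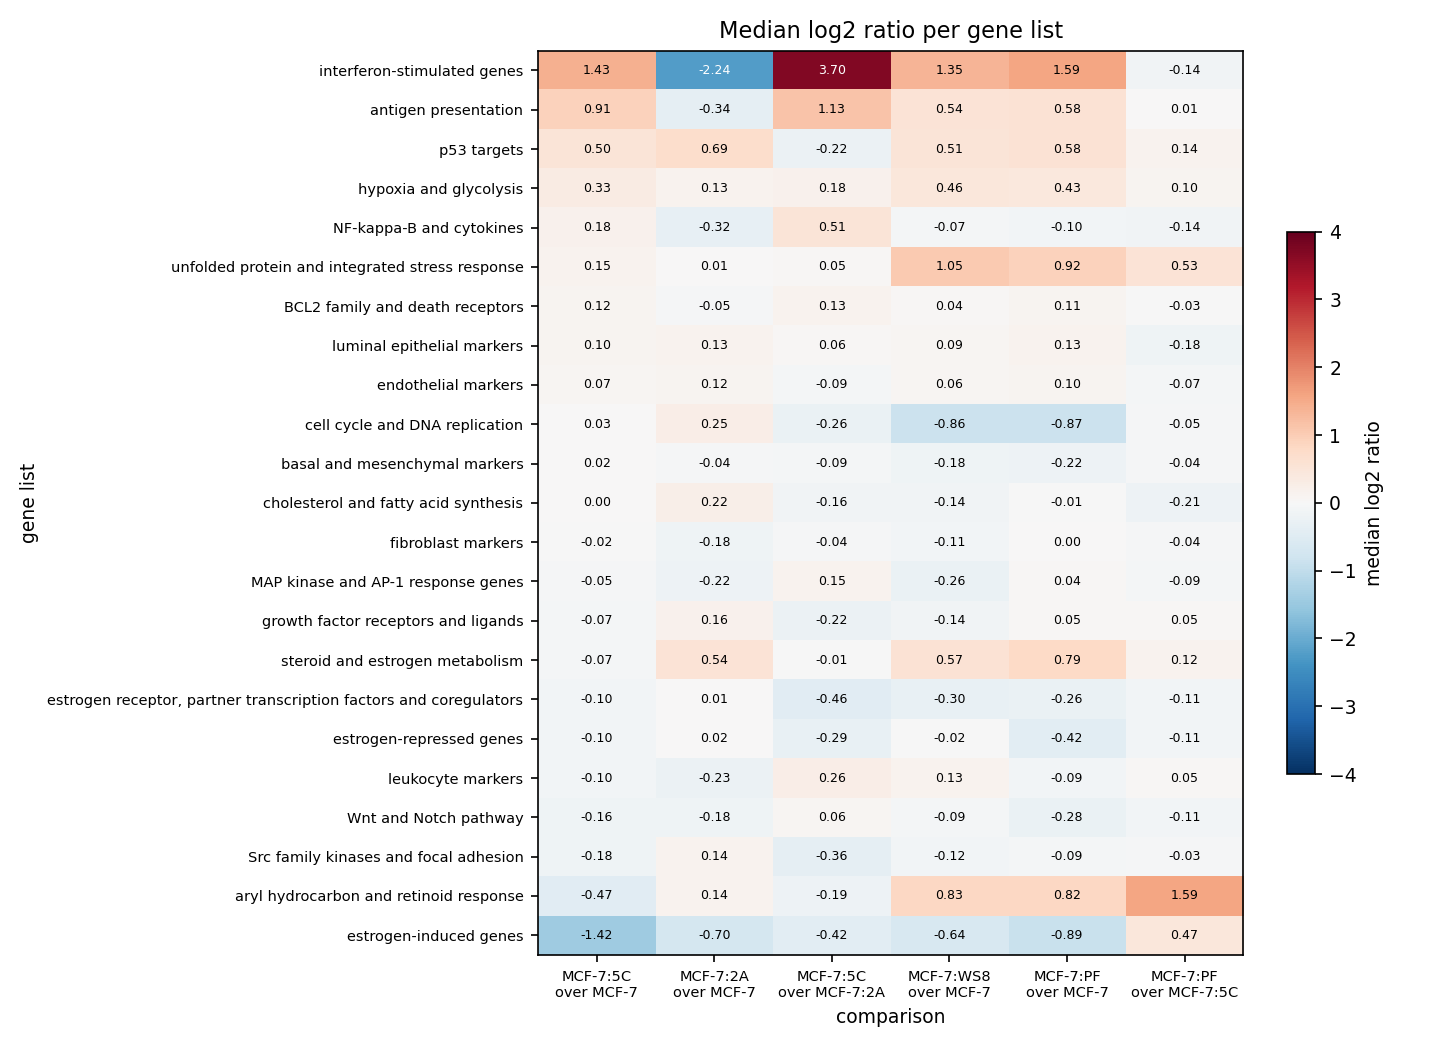
Median log2 ratio (colour scale and printed value) of each of the 23 gene lists (rows) in each of the 6 comparisons (columns). For MCF-7:PF over MCF-7:5C each gene's ratio is the mean of the direct and the indirect one. The interferon-stimulated genes range from -2.24 in MCF-7:2A over MCF-7 to 3.70 in MCF-7:5C over MCF-7:2A, and the estrogen-induced genes lie below 0 in every comparison against MCF-7.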

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

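The tests between the lines per gene and per list, the leukocyte test, the test for a damaged array region and the splits of the arrays were chosen before their results were seen, and the other tests of explanations after. The MCF-7:5C and MCF-7:2A differences from MCF-7 were tested against each other, gene by gene and per list. The median log2 difference of MCF-7:5C over MCF-7:2A was 3.698 for interferon-stimulated genes, 1.131 for antigen presentation, 0.505 for NF-kappa-B and cytokines, -0.425 for estrogen-induced genes and -0.357 for Src family kinases and focal adhesion. These 5 lists passed at the preset correlation, and with an estimated correlation 0 lists did. In addition 102 genes were called in opposite directions in the lines and differed between them. Opposite calls set the lines apart by construction, so the test of the difference adds little for these genes. They were 70 higher in MCF-7:5C and 32 higher in MCF-7:2A, fewer than the 83.21 and 79.1 of independent lists.

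The opposite position of the interferon-stimulated genes is the pattern most open to follow-up. A shared MCF-7 reference would leave no difference on 1 slide, where the smaller of the slide medians was 3.54. Dye bias common to the arrays would cancel between the lines, where 37 list members were called, and the lowest MCF-7:5C array median lay 3.126 above the highest MCF-7:2A median, which argues against a wrong label on 1 array. Leukocytes in the MCF-7:5C cultures would leave MCF-7:2A at the level of MCF-7, but the highest median of its arrays was -1.839, so they are argued against for the lower level in MCF-7:2A. For the higher level in MCF-7:5C they stay open, with 1 of the 6 markers tested, CD19, higher than in MCF-7:2A, although an established line gives no known source. The higher level was not particular to MCF-7:5C: the list median over MCF-7 was 1.354 in MCF-7:WS8 and 1.592 in MCF-7:PF. Leukocytes in the MCF-7:5C cultures would not account for those values, which rest on 1 array each. As a hypothesis that also stays open, the cells may make interferon themselves: of 4 interferon genes tested only 1, IFNL2, was above background on every array, and it was higher in MCF-7:5C than in MCF-7:2A by 3.72. The other 3, IFNL1, IFNL3 and IFNB1, were called in the same direction but were dim on 2 or 3 of the arrays. Over MCF-7, IFNL2 stood at 1.73 in MCF-7:5C, -1.99 in MCF-7:2A, 1.65 in MCF-7:WS8 and 1.62 in MCF-7:PF. Whether the probe of an interferon lambda gene also reads another was not examined, so the value of IFNL2 may not be its own.

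Replicate 1 stood apart from replicates 2 and 3 in both lines. If the MCF-7 reference labelling were the whole cause, both lines would deviate alike, but the deviations had a correlation across genes of 0.279. A damaged region of the MCF-7:2A replicate 1 array is argued against by the spread of the deviating spots, whose share in the fullest of 16 regions was 1.266 times that expected. Weak Cy3 labelling of MCF-7:2A replicate 1 stays open: the 271 probes at least 4-fold lower there were dimmer in Cy3 than in MCF-7:5C replicate 1 by a median log2 difference of -2.53, but they were chosen for being low, and lower RNA levels would give the same. Their median log2 Cy5 signal was 13.55 to 13.74 on slide 1, 11.36 to 11.82 on slide 2 and 12.40 on the MCF-7:WS8 array. On MCF-7:2A replicate 1 their median log2 Cy3 was 10.43, against 11.6 and 11.61 on replicates 2 and 3. Their Cy5 was 13.59 there, against 11.36 and 11.47. Between these replicates the reference channel thus differed more than Cy3. A growth change of the same size in both replicate 1 cultures would move the cell cycle genes alike. Their deviation was -1.11 in MCF-7:5C and 0.203 in MCF-7:2A, a difference of -1.314 ± 0.122 (SE over genes). That SE takes the genes as independent, although the list had an estimated correlation of 0.683, and it holds no spread between arrays. With 1 such array per line, the values point against an equal change without settling it. The MCF-7:2A value lay within 2 standard errors over genes of 0, so a smaller change there stays open, as does a change in MCF-7:5C replicate 1 alone.

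MCF-7:WS8 and MCF-7:PF resembled each other although their media differed. The shared reference as the whole cause would give other pairs of arrays with that labelling as high a covariance, but theirs ran from 0.097 to 0.46 and that of MCF-7:WS8 with MCF-7:PF was 0.661. A part from the reference stays open. The labels give the reference on the MCF-7:WS8 array the labelling yield of slide 1 and do not state that it was the same labelling. Estrogen in both media stays open. The higher median of the estrogen-induced genes was -0.642, but the members went both ways, with 5 higher and 17 lower in MCF-7:WS8 and 6 and 19 in MCF-7:PF, and MCF-7 itself was kept in the MCF-7:WS8 medium. One extract on both arrays cannot be excluded, since the difference of the arrays had a standard deviation of 0.371, below that of replicates across slides, although their recorded labelling yields differ (10.69 and 16.42 pmol per µg). A common origin of both lines was not tested and stays open.

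The 6 arrays of MCF-7:5C and MCF-7:2A allow 10 splits into groups of 3, too few for a share under 0.05. The real split called 1632 genes and 1 split, the real one, reached that count, while the highest other called 0. For lists, the real split shifted 5 and the highest other 6. Among the 4 splits that part every same-numbered pair, the others shifted 5, 2 and 5 lists and called 0 genes.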

How the results depend on the processing

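The dye fit, the slide block, the slides alone and the left-out replicates were planned; the fit with no minimum of measured arrays, the replicate block for lists, and the overlap within slide 2 or without MCF-7:2A replicate 1 were chosen after seeing the data. Across the alternatives, 5328 of 5794 values of named genes in the tested comparisons counted as unchanged. Of the others 279 lost and 16 gained a call, 169 moved and 2 reversed. Unchanged means the same call, or on slide 1 alone a value within 1 standard deviation of the replicates. Uncalled genes could change sign. The total holds 293 values from scaling by Aquantile, which leaves ratios unaltered. For the lists 819 of 874 counted as unchanged. In the dye fit these include the uncalled cell cycle list of MCF-7:2A, whose median went from 0.25 to -0.56.

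Counts for MCF-7:5C, MCF-7:2A and their difference, from 2754, 2391 and 1632, became 4549, 4538 and 2147 with the software's ratios, 5073, 5035 and 2097 with the deposited table, and 7942, 7402 and 2598 with no fold limit. An adjusted p under 0.01 left 948 for the difference. The dye fit called 499 and 100 genes and 59 shared genes, with larger standard errors, and turned TGFBI in MCF-7:2A to 0.586. On slide 1 alone, at 2-fold with no test, 3754 and 4682 genes passed for MCF-7:2A and the difference, and GDF15 in MCF-7:2A stood at -0.03. With replicates left out, the counts ran from 2641 to 2858, from 2231 to 2682 and from 1054 to 1750. The cell cycle median in MCF-7:5C was 0.405 within slide 2 and ran from -0.208 to 0.405 with replicates left out. An estimated correlation left 0 of 15 list shifts. Single-array counts for MCF-7:WS8, MCF-7:PF and MCF-7:PF over MCF-7:5C, from 3823, 3710 and 1287, became 7998, 6645 and 2358 with the software's ratios, 8329, 7039 and 2462 with the deposited table, and 1396, 1452 and 529 at 3-fold, and the indirect ratio alone gave 2932. The deposited table gave 2759 shared genes in place of 1039, and the software's ratios gave a return of 17.72% in place of 15.13%. The cause was not tested, except that limits and fewer arrays act by construction.

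The replicate block called 1667 genes, 1510 of them shared, ended 4 calls of named genes and changed no other call of a named gene or list. Scaling between arrays by Aquantile leaves ratios unaltered and so says nothing. Genes dim on a side (281 of those called in MCF-7:5C) have ratios that depend on the background level.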

Other observations

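The families and chromosomal runs of this part were chosen after their values were seen. Of 20 cancer-testis genes tested, which are normally expressed in testis, 8 were called higher in MCF-7:5C and 2 lower, against 0 higher and 2 lower in MCF-7:2A. GAGE12F stood at 3.86, MAGEA2B at 3.50, MAGEA12 at 2.52 and XAGE1 at 2.48 in MCF-7:5C, and at 0.08, 0.27, 0.18 and -0.02 in MCF-7:2A. In MCF-7:WS8 and MCF-7:PF, 5 and 6 were at least 2-fold higher, with MAGEA2B at 3.24 and 3.73 and CT45A5 at 2.69 and 2.85. SPANXA1 was lower in both replicated lines (-4.10 and -4.09). With the software's ratios 10 were higher and 4 lower in MCF-7:5C, and 3 higher and 5 lower in MCF-7:2A. The deposited table gave 10 and 6 of 21, and 3 and 6. Whether a probe reads several members of a family was not examined.

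Of 10 metallothionein genes, which bind zinc and copper, 3 were called lower in MCF-7:5C and 8 in MCF-7:2A, and 9 were at least 2-fold lower in MCF-7:WS8 and in MCF-7:PF. MT2A stood at -0.84, -1.48, -3.14 and -3.42 in the 4 lines in that order, and MT1E at -1.11, -1.53, -3.21 and -3.35. By the ratios of the software or of the deposited table, 4 were lower in MCF-7:5C and 8 in MCF-7:2A, and 0 were higher in either line. As for the cancer-testis genes, whether a probe reads several members was not examined, so these counts may repeat a signal.

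Neighbouring genes also moved together in places. Running medians over 15 of 13046 genes in chromosomal order were set against 100 shuffled orders. In MCF-7:5C 6 runs lay beyond every shuffled order (largest running median 1.49 in size, shuffled 1.12), in MCF-7:2A 9 (1.43, shuffled 1.02), in MCF-7:WS8 1 and in MCF-7:PF 3. Some runs overlap, and merged they make 5 separate regions in MCF-7:5C, 5 in MCF-7:2A, 1 in MCF-7:WS8 and 3 in MCF-7:PF. The MCF-7:WS8 run, from GNAO1 to ARL2BP, was also among those of MCF-7:2A and of MCF-7:PF. Of its 21 genes, 8 were lower at 2-fold in MCF-7:2A and 10 each in MCF-7:WS8 and MCF-7:PF. Over all 21 the medians were only -0.20, -0.51 and -0.28. Whether the lower genes of this run are the metallothionein genes above was not examined, so it may repeat that result. Whether a probe within a run reads several genes was not examined, so a run may repeat a signal. In MCF-7:2A the run from SBDS to GTF2I had a median of 1.06 over 30 genes and that from WBSCR23 to SEMA3E, which overlaps it, 1.06 over 31, against -0.07 and -0.17 in MCF-7:5C. In MCF-7:5C the run from SDR16C5 to TRAM1 had a median of -1.22 over 31 genes. The same genes had medians of -0.47 in MCF-7:2A, -1.07 in MCF-7:WS8 and -0.89 in MCF-7:PF, so the lower level was not particular to MCF-7:5C. The run from HLA-F to HLA-E stood at 1.23 in MCF-7:5C, -0.69 in MCF-7:2A, 1.04 in MCF-7:WS8 and 1.39 in MCF-7:PF.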
